A study of Mus musculus with 16 samples.

How the data were processed

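Total RNA from bone-marrow-derived macrophages of male WT and miR-155 KO mice was measured at 0, 6, 12 and 24 h of LPS on 16 arrays, 2 for each of 8 groups. Per the file headers, the arrays are single-colour (Cy3) Agilent arrays of 43379 spots holding 41174 probes, 4 arrays to a slide, scanned and read with Agilent Feature Extraction 10.5.1.1. The deposited scanner files give the processed intensity of each spot. Per the file headers, spatial detrending, background subtraction and multiplicative detrending were applied by that software, dim spots received a surrogate value, and replicate spots were not averaged. The deposited series table holds log2 values scaled to each array's 75th percentile, per the labels' processing notes. Its upper quartile was 8.78 to 8.79 on every array, and its values correlated with the log2 of the scanner intensities at r = 1.

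Values were computed from the scanner files. Spots that the software marked as outliers (61 to 108 per array) and 1639 control spots were removed, and no spot was saturated (0). The log2 of the remaining intensities was averaged over the spots of a probe, and the array's 75th percentile was subtracted. Of 41077 probes with a value on all arrays (97 left out because every spot was an outlier on at least 1 array), 26855 were well above background, by the software's own test, on both arrays of at least 1 group. Gene names came from the gene table of the reference by accession (26869 probes), symbol (5559) or synonym (891), and 7758 probes kept the name in the array file. The probe with the highest mean stood for each gene, which left 17659 genes, 14244 of them with a reference symbol, and 9196 detected probes shared a gene with another probe. Probe positions are those of the array file, on mm9.

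Group means were fitted with limma 3.58.1 in R 4.3.3 with empirical Bayes moderation (8 residual and 2.29 prior degrees of freedom), and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. The comparisons were LPS against 0 h at each time and 24 h against 6 h in each genotype, KO against WT at each time and averaged over the 4 times, and the difference in LPS response between genotypes, singly and in a joint F test. Only those last tests were used to say that a response differs between genotypes. Whether replicate numbers pair the samples was checked before the fits were compared. The deviations of same-numbered arrays from their group means correlated in all 28 pairs of groups (0.40 to 0.84, median 0.58), and the file headers place the 8 arrays of each number in their own scan session. The fit with the session as a term has 7 residual degrees of freedom and is given beside the other where it changes a call or moves a count by more than 1.5 times. Unless stated otherwise, values after ± are standard errors of the fit without the session, also where a p-value with the session stands beside them. With that term 9657 genes passed for the session itself.

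The design, the alternatives, 28 gene lists and the rule for naming genes were fixed before the data were examined. The lists, 17 of pathways and 11 of cell types, name 757 members, of which 669 were tested. The pathway lists are cytokines and chemokines, interferon-stimulated genes, feedback regulators, Toll-like receptor signalling, late LPS response, cell cycle, cholesterol synthesis, LXR targets, glycolysis and hypoxia, unfolded protein and amino acid response, oxidative stress, macrophage identity, alternative activation, antigen presentation, apoptosis, literature targets of miR-155, and chromosome 16 neighbours of Mir155. The cell types are neutrophils, B, T and NK lymphocytes, erythroid cells, megakaryocytes, mast cells, stromal, endothelial and dendritic cells, osteoclasts and progenitors. Lists were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. KO against WT list means were also tested by exact permutation of genotype within times (1296 arrangements, smallest possible p = 0.00154) and by exact exchange within times and sessions (256 arrangements, smallest possible p = 0.00781).

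Genes named in the text were taken by rule among genes with an ordinary symbol that passed the threshold and whose arrays did not overlap between the groups. The rule took the 6 largest rises and 6 largest falls in WT and the 4 and 4 largest in KO for LPS against 0 h, the 4 and 4 largest for 24 h against 6 h. It took 10 and 10 for KO against WT averaged over times if the sign was the same at every time, 5 and 5 at each time, the 8 smallest p-values of the F test, and up to 4 called members each way of every list. It also named Tnf, Il6, Il1b, Il10, Il12b, Ifnb1, Nos2, Arg1, Arg2, Socs1, Inpp5d, Spi1, Cebpb, Bach1, Jarid2 and Csf1r, called or not, and the host gene of Mir155, for which the array has 0 probes. Of the genes so named the text prints a part, and some are not reported here. For LPS these are examples whose call held when any single array was left out, apart from Tnf and genes named without a call. Members of the target list and of the interferon-stimulated list printed for KO against WT, and every gene said to be chosen after its value was seen, lie outside that rule or below the threshold.

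On simulated data with 200 changed genes among 17659, the fit recovered 25.5% of 4-fold changes in the comparison of 6 h with 0 h in WT (73.5% with the session), 27.5% for KO against WT at 6 h (77.5% with the session) and 82.5% for KO against WT averaged over times (97.5% with the session). Of 2-fold changes it recovered 0, 0 and 19.5% (0, 0 and 69% with the session). A 2-fold difference at a single time was thus out of reach when as few as 200 genes changed. Where many genes change, the adjusted threshold is easier to pass. In the real comparison of 6 h with 0 h in WT, 4210 of the 4489 genes called were at least 2-fold, and the others were smaller. For KO against WT averaged over times, 100 simulated lists of 60 genes were raised by 0.1 on the log2 scale. At unadjusted p under 0.05 camera passed 99 of them with the preset and 83 with an estimated correlation. The simulated genes varied independently. These shares therefore do not hold for lists of correlated genes, such as the interferon-stimulated genes (estimated correlation 0.43).

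Alternatives were quantile normalization, scaling to the array median, normexp background correction with an offset of 50, no filter on dim probes, and only probes well above background on all 16 arrays. Others were all probes, values as deposited, the slide as a fixed or random block, the session as a block, trended and robust moderation, array weights, only the arrays compared, an added 2-fold threshold, and leaving out each array. Other tools were Python 3.11.15, pandas 2.3.3, numpy 2.4.6, matplotlib 3.10.9 and the R package data.table (1.17.8). A planned search for miR-155 seed sites in 3′ untranslated regions was not run, because the reference holds no transcript sequences, and sequences of the probes were searched in its place. Quality metrics of the scanner files other than those named were not used here.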

Results

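Bone-marrow-derived macrophages from male C57BL/6Jax mice were profiled before and during stimulation with LPS, a component of the outer membrane of Gram-negative bacteria that is sensed by the receptor Tlr4. Marrow cells of wild-type (WT) mice and of mice lacking the microRNA miR-155 (KO) had been grown for 9 days in 10 ng/mL M-CSF, the growth factor that turns marrow progenitors into macrophages. LPS was given at 100 ng/mL. Total RNA came from unstimulated cells (0 h) and from cells after 6, 12 or 24 h of LPS, which gives 8 groups of 2 samples, each on its own single-colour array. The design asks which transcripts respond to LPS in each genotype, and which differ between the genotypes at a given time or in the size of the response. The upper quartile of the probe signal was between 291.0 and 775.7 scanner units per array, and 56.2% to 67.6% of probes were well above background. After filtering, 17659 genes were tested. The labels do not say whether replicates came from separate cultures or animals. The p-values therefore measure the spread between these samples, and the number of arrays limits the precision of every value.

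The array has no probe for Mir155 or its host gene, so the loss of miR-155 could not be checked on these arrays. Replicates of a group correlated at r = 0.9554 to 0.9734 across genes, which are not independent replicates. The first principal component held 49.1% of the variance and separated unstimulated from stimulated arrays. The second held 20.4% and separated the replicates. The 8 arrays numbered 1 were scanned in a first session and the 8 numbered 2 in a later session, and in all 8 groups the session 1 array lay below the session 2 array. Results with a term for the session are therefore given wherever they differ from those without it.

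**Figure D1:**
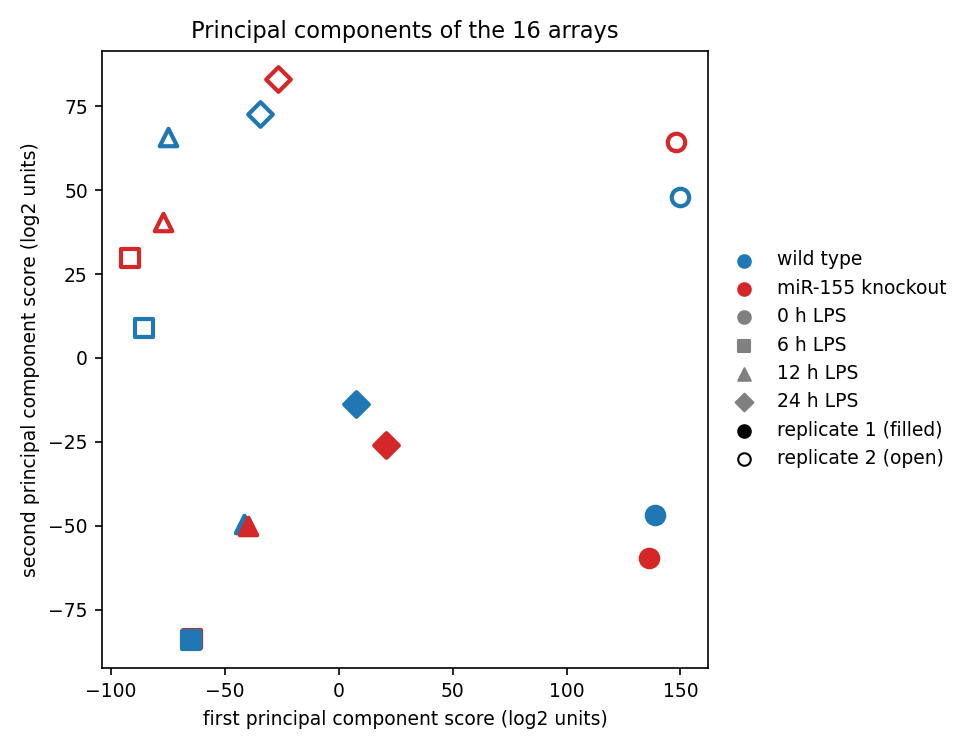
First against second principal component of the 16 arrays, in log2 units, with genotype by colour, hours of LPS by shape, and filled and open symbols for the first and second scan session. The first component (49.1% of variance) follows LPS and the second (20.4%) the session.

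In WT macrophages, 6 h of LPS raised a broad inflammatory and antiviral programme and lowered genes of the cell cycle. On the log2 scale the chemokine Cxcl9 rose by 12.91 ± 0.68 (standard error, 2 arrays per group). Acod1, which makes the metabolite itaconate, rose by 11.67 ± 0.94 and the early activation marker Cd69 by 11.53 ± 0.88. The acute-phase gene Saa3 rose by 11.16 ± 1.43 and the protease inhibitor Serpina3g by 11.05 ± 0.50. Il1b, which encodes interleukin 1 beta, rose by 8.89 ± 0.92. Several genes were not well above background at 0 h and have only lower bounds. Each bound sets the bright group's mean against, on each array of the dim group, the higher of the probe's own signal and the lowest signal of any probe well above background. By that measure Il6 was at least 12700-fold higher and Il12b, a subunit of interleukins 12 and 23, at least 3530-fold. The chemokine Cxcl11 was at least 3990-fold higher, the endothelin gene Edn1 at least 2200-fold, the interferon gene Ifnb1 at least 838-fold and the inducible nitric oxide synthase Nos2 at least 744-fold. Among the largest decreases were Fam214a (−6.88 ± 0.39), Plekhg3 (−6.66 ± 0.49) and the kinetochore gene Cenpf (−6.55 ± 1.11). The cannabinoid receptor Cnr2 fell by 6.28 ± 0.90 and Cebpa, a transcription factor of myeloid cells, by 6.01 ± 1.21.

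By limma with Benjamini-Hochberg adjustment, 4489 genes changed at 6 h in WT, 2231 higher and 2258 lower. With the session as a term the count was 8047. Each of the 4489 moved the same way in both sessions. The call largely ensures this, because the 2 arrays of a group are its 2 sessions. Over all tested genes the sessions' fold changes correlated at r = 0.85 across genes, which are not independent replicates. The count was 2764 without the second 0 h array and 2780 without the second 6 h array. Tnf was higher by 5.36 ± 1.50 (adjusted p = 0.024; sessions 7.80 and 2.91). It missed the threshold without the first 0 h array (3.16), the first 6 h array (5.12) or the second 6 h array (5.60). Il10 was higher by 3.71 ± 1.94 and passed only with the session (adjusted p = 0.199, then 0.00319). Arg1 (−0.81 ± 1.81), Arg2 (1.14 ± 1.47), Bach1 (−0.19 ± 1.56) and Csf1r (−0.51 ± 0.67) passed in neither fit.

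Gene lists showed what the programme was made of at 6 h. All 55 interferon-stimulated genes rose (55 adjusted over the list alone), with a median of 5.84 and session medians of 5.53 and 5.94. They include Ifi205 (11.13 ± 0.85) and the guanylate-binding protein gene Gbp6 (at least 1400-fold). Of 36 inflammatory cytokines and chemokines 27 rose and 1, the growth factor gene Vegfa, fell (28 and 1 adjusted over the list alone). Their median was 4.75 (sessions 6.05 and 4.71), and Vegfa fell by 3.96 ± 0.61. Of 37 genes of the late LPS response 32 rose (32 over the list alone), with a median of 6.36, or 6.04 with bounds (sessions 6.05 and 6.77). Of 31 genes of antigen presentation and co-stimulation 22 rose (24 over the list alone), with a median of 2.73 (sessions 2.39 and 2.98). Among them were the co-stimulatory receptor Cd40 (8.40 ± 0.90), Cd86 (5.06 ± 0.66), Cd274, which encodes PD-L1 (6.53 ± 0.44), and Tnfsf4 (at least 201-fold). Of 33 feedback regulators of NF-kB and Toll-like receptors 20 rose and 1 fell (23 and 2 over the list alone), with a median of 3.01, or 2.94 with bounds (sessions 2.93 and 2.69). Socs1, a brake on cytokine signalling, rose by 7.65 ± 0.28, Traf1 by 8.36 ± 0.48 and Tnip3 by 6.47 ± 0.42. These 5 lists passed camera at adjusted p from 2.55e-46 (interferon) to 8.94e-11 (feedback). They also passed with an estimated correlation, at adjusted p = 0.0207 for the late list and 0.0495 for each of the others.

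Of 50 cell cycle genes 37 fell and 0 rose at 6 h (39 and 0 adjusted over the list alone), with a median of −2.96 (sessions −2.82 and −3.08). The mitotic kinesin Kif23 fell by 5.67 ± 0.70, Cdc20, an activator of the anaphase-promoting complex, by 5.23 ± 0.32, and the cyclin Ccna2 by 4.95 ± 0.75. Of 33 apoptosis regulators 14 rose and 1 fell (16 and 2 over the list alone), with a median of 0.78 (sessions 0.88 and 0.94). The death ligand Tnfsf10 rose by 8.30 ± 0.64, the death receptor Fas by 4.03 ± 0.37 and its inhibitor Cflar by 4.07 ± 0.28. Of 33 Toll-like receptor signalling genes 10 rose and 2 fell (13 and 3 over the list alone), with a median of 0.94 (sessions 0.76 and 1.06). The adaptor Myd88 rose by 3.31 ± 0.36 and the kinase Irak2 by 3.48 ± 0.49. Of 34 macrophage identity genes 10 rose and 4 fell (12 and 4 over the list alone), with a median of 0.50, which was −0.08 after quantile normalization. The scavenger receptor Marco rose by 6.63 ± 1.11 and the high-affinity IgG receptor Fcgr1 by 3.56 ± 0.52. Camera called these 4 lists at adjusted p = 2.25e-16, 0.000241, 0.00571 and 0.0364, the last being 0.0703 with the session. All 4 were lost with an estimated correlation (adjusted p = 0.149, 0.362, 0.212 and 0.44).

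Metabolic and stress lists moved little as groups at 6 h in WT, and camera passed none of them. Of 28 genes of glycolysis and the hypoxia response 6 rose and 1 fell (the same over the list alone), with a median of 0.20. The glycolytic activator Pfkfb3 rose by 4.55 ± 0.36. Of 20 oxidative stress genes 3 rose (3 over the list alone), with a median of 0.18. They were the mitochondrial dismutase Sod2 (4.45 ± 0.34), Prdx5 (2.96 ± 0.43) and Keap1 (2.34 ± 0.33). Of 25 genes of the unfolded protein and amino acid response 1 rose and 3 fell (the same over the list alone), with a median of 0.15. Sesn2, a stress-induced inhibitor of mTOR, fell by 2.32 ± 0.39. Of 24 cholesterol synthesis genes 3 fell (3 over the list alone), with a median of −0.28. Of 20 LXR targets and lipid efflux genes 1 rose and 2 fell (1 and 1 over the list alone), with a median of −0.13. Of 20 alternative activation markers 4 rose and 3 fell (the same over the list alone), with a median of −0.17 and a mean of 0.28.

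Literature targets of miR-155 went both ways at 6 h in WT. Of 60 tested 15 rose and 9 fell (17 and 12 adjusted over the list alone), with a median of 0.56. The adhesion molecule Vcam1 rose by 6.43 ± 0.35 and the receptor chain Il13ra1 by 4.50 ± 0.62. The DNA repair gene Msh6 fell by 3.33 ± 0.33 and Inpp5d, the phosphatase SHIP1, by 3.21 ± 0.37. Inpp5d also fell without miR-155, its KO means being 4.56 at 0 h and 1.70 at 6 h, against 4.61 and 1.40 in WT. Of 20 listed neighbours of Mir155 on chromosome 16, 5 rose (5 over the list alone), with a median of 0.30. Usp25, which removes ubiquitin from proteins, rose by 3.45 ± 0.39. Neither list passed camera.

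Marker lists of other cell types were read in the same way at 6 h. Of 13 dendritic cell markers 7 rose and 1 fell (8 and 1 adjusted over the list alone), with a median of 2.86 (sessions 1.81 and 2.97). Camera called them at adjusted p = 0.000445, and at 0.0495 with an estimated correlation. The chemokine Ccl17 rose by 6.11 ± 0.37 and the actin-bundling gene Fscn1 by 6.04 ± 1.01, and the chemokine Ccl22 was at least 67.6-fold higher. Of 14 stromal markers 3 rose (3 over the list alone), with a median of 1.39 (sessions 1.07 and 1.33), among them Pdgfrb (4.60 ± 0.84). Camera gave adjusted p = 0.0112, lost with an estimated correlation (adjusted p = 0.105). Of 8 T and NK markers 2 rose (2 over the list alone), the kinase Lck (7.48 ± 0.40) and the receptor chain Cd247 (6.70 ± 0.65). The median was 1.32, or 1.09 with bounds, and camera gave adjusted p = 0.0299, or 0.052 with the session. That call was lost with an estimated correlation (adjusted p = 0.44). After normexp background correction with the local background capped, the medians of dendritic and of T and NK markers were 1.65 and 0.71.

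The other marker lists did not pass camera at 6 h. Of 15 neutrophil markers 0 passed by limma (median −0.04). Of 10 B lymphocyte markers 1 fell (median 0.34, mean −0.19). Of 9 erythroid markers 2 rose and 1 fell (median 0.79), and of 8 megakaryocyte and platelet markers 1 rose and 2 fell (median 0.44). Of 5 mast cell and basophil markers 2 rose and 1 fell (median 1.24). Of 9 endothelial markers 2 rose and 1 fell (4 and 1 adjusted over the list alone; median 1.54), with the VEGF receptor Kdr up by 4.55 ± 0.63. Of 11 osteoclast markers 3 rose (4 and 1 over the list alone; median 0.49), with the phosphatase Acp5 up by 4.35 ± 0.69 and the carbonic anhydrase Car2 by 6.02 ± 1.01. Of 8 progenitor markers 1 fell (median 0.39). For the lists without a second count the numbers were the same over the list alone.

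At 12 h of LPS in WT, complement factor B, Cfb, had risen by 11.80 ± 0.70, the chemokine Ccl5 by 8.98 ± 1.61, Slfn4 by 10.67 ± 1.14 and the histamine-making enzyme Hdc by 10.07 ± 0.96. Lower than at 0 h were Rasgrp3, which activates Ras (−8.38 ± 1.02), the organic anion carrier Slco2b1 (−7.91 ± 0.58) and the mitotic kinase Pbk (−7.22 ± 1.31). The sialyltransferase St6gal1 fell by 7.07 ± 0.44 and the mannose receptor Mrc1 by 3.75 ± 0.52, and Cenpf was at least 145-fold lower. At 24 h Cfb was still up by 11.70 ± 0.70, the formyl peptide receptor Fpr1 by 9.85 ± 0.61 and Il1b by 6.32 ± 0.92. Mrc1 was down by −5.61 ± 0.52, the transcription factor Egr2 by −5.17 ± 0.74 and the cyclin Ccnb2 by −5.82 ± 0.66.

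By limma 3416 genes changed at 12 h in WT, 1709 higher and 1707 lower (6645 with the session), and 1948 at 24 h, 991 higher and 957 lower (4842 with the session). Each moved the same way in both sessions, which the call again largely ensures. Over all tested genes the sessions correlated at r = 0.83 at 12 h and 0.81 at 24 h across genes, not independent replicates. The 12 h count was 1713 without the second 12 h array and 1727 without the second 0 h array. The 24 h count was 801 without the second 24 h array, 847 without the second 0 h array and 1294 without the first 0 h array. Tnf (4.01 ± 1.50, adjusted p = 0.0912), Il10 (3.08 ± 1.94, 0.326) and Csf1r, the receptor for M-CSF (−1.05 ± 0.67, 0.336), passed at 12 h only with the session, at 0.0285, 0.0104 and 0.0108. Tnf also passed at 12 h when the second 0 h WT array was left out (6.21), or either 0 h KO array (4.01 each). Csf1r passed at 24 h only with the session (−0.90 ± 0.67, adjusted p = 0.484, then 0.0303). Inpp5d, lower at 6 h, differed from 0 h by −0.59 ± 0.37 at 12 h and −0.30 ± 0.37 at 24 h, neither past the threshold.

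All 55 interferon-stimulated genes were still raised at 12 h (median 5.25, sessions 4.77 and 5.72) and at 24 h (median 4.70, session means 4.75 and 5.82). Cxcl11 was at least 4130-fold and at least 2170-fold above 0 h. The list passed with an estimated correlation at 24 h (adjusted p = 0.0375) and not at 12 h (adjusted p = 0.0574 with an estimated correlation). Late LPS response genes passed at both times, with 31 and 26 of 37 raised (33 and 31 adjusted over the list alone) and medians of 5.76 and 4.58. Their adjusted p was 0.0123 and 0.0127 with an estimated correlation. Of the cytokines 22 rose and 1 fell at 12 h (23 and 1 over the list alone), with a median of 3.62, or 3.57 with bounds. At 24 h 15 rose (18 over the list alone), with a median of 2.39, or 2.21 with bounds, and Il6 went from at least 1220-fold to at least 173-fold above 0 h. Feedback regulators rose in 16 and 12 cases at 12 and 24 h (18 and 12 over the list alone) and antigen presentation genes in 20 and 19 (22 and 21 over the list alone). Cell cycle genes fell in 35 and 31 cases (38 and 37 over the list alone). For cytokines, feedback regulators, antigen presentation and cell cycle, camera's calls were lost with an estimated correlation at 12 h (adjusted p = 0.0588, 0.0636, 0.0588 and 0.105) and at 24 h (adjusted p = 0.085, 0.085, 0.0815 and 0.085).

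A part of the cholesterol synthesis genes fell late in WT. At 24 h 5 of 24 fell (7 adjusted over the list alone) and all 24 were below 0, with a median of −1.52 (sessions −0.79 and −2.23). The sterol carrier gene Stard4 (−2.70 ± 0.43) was among them. Camera gave adjusted p = 0.0223 at 12 h and 8.67e-07 at 24 h, both lost with an estimated correlation (adjusted p = 0.76 and 0.362). Genes of the unfolded protein and amino acid response had a median of 0.51 at 24 h (sessions 0.76 and 0.13), which was 0.15 after quantile normalization and 0.86 after scaling to the median, with 3 of 25 raised (3 over the list alone). The stress-induced pseudokinase Trib3 rose by 3.26 ± 0.47 and Chac1, which degrades glutathione, by 3.51 ± 0.39. Camera gave adjusted p = 0.0134, lost with an estimated correlation (adjusted p = 0.362). Alternative activation markers had a median of −1.15 at 24 h, with 4 of 20 raised and 6 lowered (4 and 7 over the list alone), Mrc1 and Egr2 among the latter. Camera called them only with the session (adjusted p = 0.0846, then 0.0478), lost with the session and an estimated correlation (adjusted p = 0.153). The same held for LXR targets (median −0.58, or −0.22 after scaling to the median; adjusted p = 0.254, then 0.0478), although the LXR gene Nr1h3 itself was up by 3.74 ± 0.70 at 12 h. It held too for neutrophil markers (median −1.15, 14 of 15 below 0, adjusted p = 0.0846, then 0.0023). With the session and an estimated correlation these lists were at adjusted p = 0.319 and 0.187. Dendritic cell markers had a median of 2.01 at 24 h, or 0.90 with bounds. Camera called them at adjusted p = 0.0445, and not with the session (0.104) or with an estimated correlation (adjusted p = 0.226). Stromal markers had medians of 1.43 at 12 h and 0.85 at 24 h (sessions 0.57 and 1.15 at 24 h), with camera at adjusted p = 0.00754 and 0.0445. Both calls were lost with an estimated correlation (adjusted p = 0.101 and 0.202). After normexp with a capped background the 24 h medians shrank to −0.55 for alternative activation, −0.54 for neutrophil, 0.46 for dendritic cell and 0.47 for stromal markers.

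**Figure D2:**
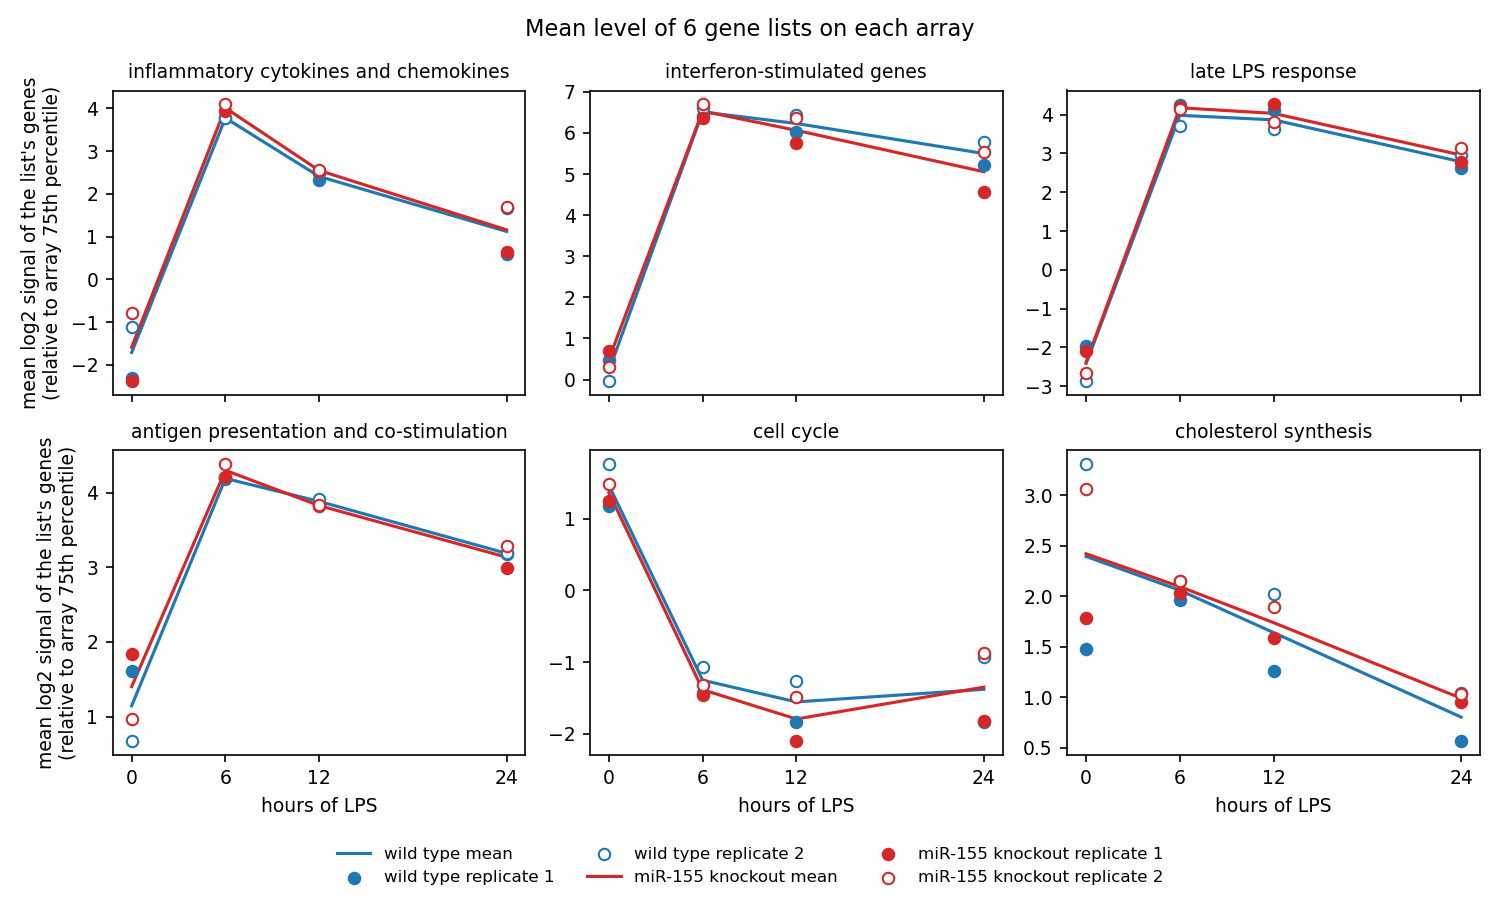
Mean level of 6 gene lists per array, in log2 units relative to the array's upper quartile, against hours of LPS, with WT and KO by colour and the scan sessions by filled and open symbols. Interferon-stimulated genes, cytokines, late LPS genes and antigen presentation genes were higher after LPS, cell cycle genes lower, and cholesterol synthesis genes lowest at 24 h (WT median −1.52).

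Between 6 and 24 h in WT several early cytokines declined, and some genes of the amino acid response and some lowered at 6 h rose. Il6 fell by 6.20 ± 0.83, Il12b fell by 6.17 ± 0.65, and Ccl22 fell by 5.65 ± 0.37. Lck fell by 6.52 ± 0.40, Vcam1 fell by 5.28 ± 0.35, Macc1 fell by 6.93 ± 1.08 and Plaur, the urokinase receptor, fell by 4.10 ± 0.57. The uridine phosphorylase Upp1 was at least 32.1-fold lower. Trib3 rose by 5.22 ± 0.47, Chac1 by 3.52 ± 0.39 and Sesn2 by 3.13 ± 0.39. Cnr2 rose by 5.85 ± 0.90, Plekhg3 by 5.19 ± 0.49, Inpp5d by 2.91 ± 0.37 and Msh6 by 2.61 ± 0.33. By limma 1848 genes changed, 990 higher and 858 lower, or 5312 with the session. Sessions correlated at r = 0.78 across genes, not independent replicates. The share that was higher was 53.6%, against 67.9% (630 higher, 298 lower) when arrays were scaled to their median and 63.8% (1302 and 740) after quantile normalization. The count was 552 without the first 24 h array, 720 without the first 6 h array, 770 without the second 6 h array and 934 without the second 24 h array. With the session as a term Il10 (−2.39 ± 1.94, adjusted p = 0.51, then 0.0394) and Nos2 (−2.40 ± 0.80, 0.089, then 0.0454) also passed.

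Of the cytokines 11 fell and 1 rose between 6 and 24 h in WT (19 and 1 adjusted over the list alone), with a median of −2.68, or −2.54 with bounds (sessions −3.27 and −1.90). Of the interferon-stimulated genes 12 fell (16 over the list alone), with a median of −1.11 (sessions −1.28 and −0.87). Feedback regulators fell in 8 cases (9 over the list alone; median −1.44) and alternative activation markers in 5 (7 over the list alone; median −1.61). Dendritic cell markers fell in 3 cases (4 over the list alone; median −1.97), late LPS genes in 6 (8; median −0.91) and cholesterol genes in 2 (6; median −1.41). Antigen presentation genes fell in 3 cases (3 over the list alone; median −0.77) and T and NK markers in 2 (2; median −1.24, or −0.91 with bounds). After quantile normalization the medians were −0.66 for interferon-stimulated genes, −0.46 for late LPS genes, −0.47 for antigen presentation genes and −0.72 for T and NK markers. Camera called these 9 lists at adjusted p between 1.57e-08 and 0.0112, and all were lost with an estimated correlation (adjusted p between 0.157 and 0.553). Of the unfolded protein and amino acid genes 6 rose (6 over the list alone), with a median of −0.02 and a mean of 0.55 (adjusted p = 0.0533). Neutrophil markers passed only with the session (median −1.31, or −1.19 with bounds; adjusted p = 0.0879, then 0.00362), lost with an estimated correlation besides (adjusted p = 0.289).

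In KO macrophages each time of LPS was compared with 0 h in the same way. At 6 h Acod1 rose by 11.93 ± 0.94, Saa3 by 11.45 ± 1.43, Cd69 by 11.20 ± 0.88, Hdc by 10.92 ± 0.96 and Il1a, which encodes interleukin 1 alpha, by 10.43 ± 1.30. Il1b rose by 9.33 ± 0.92, Cd40 by 8.52 ± 0.90 and Socs1 by 7.29 ± 0.28. Il6 was at least 14800-fold higher, Cxcl9 at least 7580-fold, Il12b at least 4560-fold, Ifnb1 at least 765-fold and Nos2 at least 677-fold. Plekhg3 fell by 6.95 ± 0.49, Cnr2 by −6.94 ± 0.90, the cell cycle regulator E2f2 by −6.89 ± 0.51, Cebpa by −5.88 ± 1.21 and Cdc20 by −5.23 ± 0.32. At 12 h Cfb was up by 11.84 ± 0.70 and the integrin Itgb3 by 4.88 ± 0.45. At 24 h Fpr1 was up by 10.43 ± 0.61 and Chac1 by 3.60 ± 0.39. The prostaglandin-degrading enzyme Hpgd (−7.56 ± 1.19), Mrc1 (−5.50 ± 0.52) and the proton pump subunit Atp6v0d2 (−5.09 ± 0.69) were down at 24 h. Between 6 and 24 h Il6 fell by 5.80 ± 0.83 and the chemokine Cx3cl1 fell by 6.38 ± 0.38, Ccl22 was at least 58-fold lower, and Trib3 rose by 5.05 ± 0.47.

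By limma 4598 genes changed at 6 h in KO (2165 higher, 2433 lower), 3430 at 12 h (1676 and 1754), 1749 at 24 h (877 and 872) and 2275 between 6 and 24 h (1249 and 1026). With the session the counts were 7719, 6772, 4261 and 5673. Fold changes of the sessions correlated at r = 0.84, 0.80, 0.73 and 0.75 across genes, which are not independent replicates. Leaving out the second 0 h array gave 2969, 1824 and 776 genes at 6, 12 and 24 h, and leaving out the second array of the LPS time gave 2972, 1706 and 759. Between 6 and 24 h the counts were 925 and 1210 without the first or second 6 h array and 949 and 1376 without the first or second 24 h array. Some genes passed only with the session. These were Il10 at 6 h (3.44 ± 1.94, adjusted p = 0.24, then 0.00474), Tnf at 12 h (4.26 ± 1.50, 0.0748, then 0.0218) and Csf1r at 12 h (−0.83 ± 0.67, 0.456, then 0.03). Cebpb did so at 24 h (1.86 ± 0.53, 0.0543, then 0.000419). Between 6 and 24 h Il10 (−3.32 ± 1.94, 0.319, then 0.00891) and Spi1 (−0.90 ± 0.36, 0.131, then 0.0489) did so as well.

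Lists were read at 6, 12 and 24 h in KO as in WT. Interferon-stimulated genes rose in 55, 55 and 54 cases (55 each adjusted over the list alone), with medians of 5.84, 4.91 and 3.85. Their adjusted p was 0.045, 0.0758 and 0.0445 with an estimated correlation. Cytokines rose in 27, 21 and 10 cases (28, 25 and 11 over the list alone), with medians of 5.11, 3.57 and 1.99, or 5.11, 3.42 and 1.95 with bounds. Their adjusted p was 0.045, 0.0824 and 0.103 with an estimated correlation. Late LPS genes rose in 32, 31 and 26 cases (32, 33 and 31 over the list alone), with medians of 6.67, 6.01 and 5.08, the first being 6.35 with bounds. Their adjusted p was 0.0163, 0.0126 and 0.00908 with an estimated correlation. Cell cycle genes fell in 38, 34 and 30 cases (40, 38 and 37 over the list alone), with medians of −2.99, −3.05 and −2.62, the first pair being −2.71 and −2.91 with bounds. Their adjusted p was 0.143, 0.0994 and 0.103 with an estimated correlation. Cholesterol genes had a median of −1.41 at 24 h (camera adjusted p = 1.79e-06, lost with an estimated correlation at adjusted p = 0.368).

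LXR targets fell in 5 of 20 cases at 24 h in KO (5 adjusted over the list alone), with a median of −0.84. Camera gave adjusted p = 0.0265, lost with an estimated correlation (adjusted p = 0.113), and at 12 h it called them only with the session (median −0.49, adjusted p = 0.215, then 0.0346, and 0.315 with an estimated correlation besides). Glycolysis genes passed at 6 h in KO, with 8 of 28 raised and 1 lowered (the same over the list alone) and a median of 0.41, which was −0.05 after quantile normalization. Camera gave adjusted p = 0.0309, and they passed neither with the session (0.0763) nor with an estimated correlation (adjusted p = 0.462). Neutrophil markers passed at 24 h only with the session (adjusted p = 0.09, then 0.00658), lost with an estimated correlation besides (adjusted p = 0.241). Their median was −1.02, or −0.94 with bounds, and 0.10 after normexp background correction. Between 6 and 24 h the unfolded protein and amino acid list had a median of 0.43. Camera called it at adjusted p = 0.0162, and it passed neither with the session (0.0623) nor with an estimated correlation (adjusted p = 0.384). Other lists went down over that time in KO. From 6 to 24 h the mean level went from 4.01 to 1.16 for cytokines, from 6.53 to 5.06 for interferon-stimulated genes and from 0.20 to −1.73 for dendritic cell markers.

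**Figure D3:**
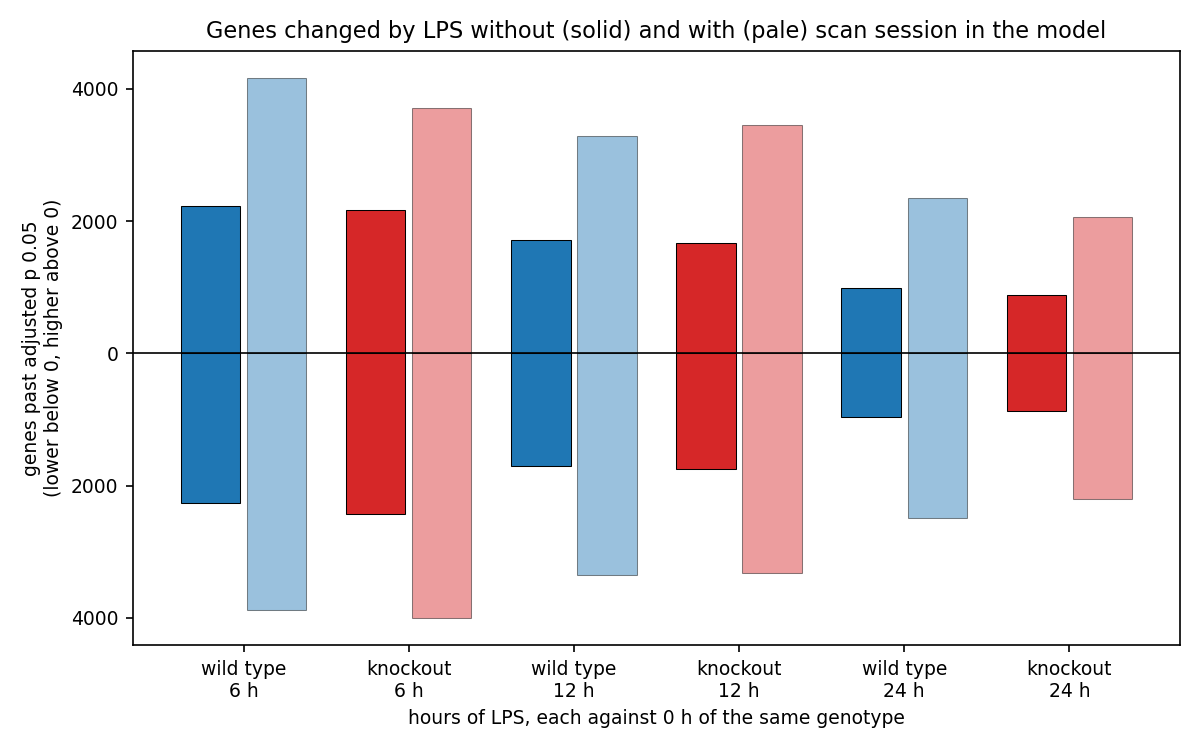
Number of genes past an adjusted p of 0.05 after LPS, higher above 0 and lower below it, for WT and KO at 6, 12 and 24 h, with solid bars for the fit without and pale bars for the fit with a term for scan session. Counts without the term fell from 4489 at 6 h to 1948 at 24 h in WT and from 4598 to 1749 in KO.

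Set side by side, the LPS responses of the genotypes correlated at r = 0.962, 0.942 and 0.929 at 6, 12 and 24 h across genes, which are not independent replicates. The slopes of KO on WT were 0.99, 0.98 and 0.94. Of the genes called in either genotype, 5053 of 5063, 4008 of 4018 and 2243 of 2245 had the same direction, and 4024, 2828 and 1452 were called in both. The difference in response itself was tested for every gene by limma. It called 0 genes at 6 h (47 at unadjusted p under 0.05, and 0 adjusted with the session), 0 at 12 h (87 and 1) and 0 at 24 h (63 and 0). A joint test of the 3 times called 0 genes (78 at unadjusted p under 0.05, and 2 adjusted with the session). A call in 1 genotype and not the other therefore does not show a difference between them.

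Averaged over the 4 times, limma called 3 genes between KO and WT. The count was 7 with the slide as a random block, 2 with the slide as a fixed block, where Cbr1 lost its call (2.67), and 0 after normexp background correction. Rptoros, named for lying opposite the mTOR partner gene Rptor and listed on the array as A430071A18Rik, was higher in KO by 4.54 ± 0.36 (adjusted p = 0.00139; sessions 4.05 and 5.02). That mean includes 12 and 24 h, when no WT array was well above background, and with those times at their bounds it was 3.83. Cbr1, which encodes a carbonyl reductase, was higher by 2.68 ± 0.30 (adjusted p = 0.0184; sessions 2.34 and 3.03). Mrpl39, which encodes a protein of the mitochondrial ribosome, was lower by −2.01 ± 0.16 (adjusted p = 0.00139; sessions −1.89 and −2.13). Rptoros and Cbr1 were higher in all 8 pairs of the same time and session, and Mrpl39 was lower in 7 of 8. Pairs of 1 session may share cultures. Neither the pairs, here and below, nor the 4 times in the averaged test are known to be independent. In mm9 coordinates the Rptoros probe lies on chromosome 11 at 119682498 to 119682557 and the Cbr1 probe on chromosome 16 at 93610497 to 93610556. The Mrpl39 probe spans 84718622 to 84724086 on chromosome 16, further apart than the probe is long, so it crosses an exon junction. Mir155 lies on the same chromosome, and Mrpl39 is in the list of its neighbours. Each gene has 1 probe. With the session 4 genes passed, the added gene being Btbd11 (1.49 ± 0.27, or ± 0.17 with the session, adjusted p = 0.611, then 0.0329), which was singled out after its value was seen. At unadjusted p under 0.05 there were 240 genes, and the sessions' differences correlated at r = 0.23 across genes, not independent replicates. The call for Cbr1 was lost when any of 13 of the 16 arrays was left out, that is, every array except both WT arrays of 12 h and the first WT array of 0 h. Its difference stayed between 2.41 and 2.95 over all 16.

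By time, limma called 0 genes between KO and WT at 0 h (43 at unadjusted p under 0.05, and 1 adjusted with the session), 0 at 6 h (147 and 2), 2 at 12 h (167 and 3) and 0 at 24 h (213 and 0). Both genes at 12 h moved alike in the sessions, which the call largely ensures. Mrpl39 was lower by −3.78 ± 0.32 (adjusted p = 0.00402; sessions −3.60 and −3.95). The extracellular superoxide dismutase gene Sod3 was higher by 2.89 ± 0.31 (adjusted p = 0.0198; sessions 3.04 and 2.74). It was named after its value was seen and was well above background only on the KO arrays of 12 h, so its difference has only a bound, at least 1.7-fold. The 12 h count was 0 without the first WT or the second KO array of 12 h, where Mrpl39 stood at −3.77 and −3.59. It was 5 without the second WT array of 12 h and 1 without the first KO array of 12 h or any WT array of another time or KO array of 6 h. At 24 h it was 1 without the second WT array of 24 h. With the session, Rptoros passed at 0 h (4.65 ± 0.73, adjusted p = 0.0433), 6 h (4.76 ± 0.73, 0.0352) and 12 h (4.80 ± 0.73, 0.0109). These errors are those of the fit without the session, and with it the error was 0.47 at each of these times. Noxa1, an activator of NADPH oxidase also named after its value was seen, passed at 6 h with the session (−2.30 ± 0.80, or ± 0.25 with the session, 0.0388). No KO array of 6 h was well above background for it, so the decrease has only a bound, at least 2.44-fold. Rptoros was not well above background on any WT array at 12 or 24 h, where KO was at least 13.4-fold and at least 4.57-fold higher.

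Mrpl39 did not differ detectably between the genotypes at 0 h (−0.04 ± 0.32). In KO it fell by 2.17 ± 0.32 after 6 h of LPS, fell by 3.76 ± 0.32 after 12 h and fell by 1.22 ± 0.32 after 24 h. Its WT means were 2.28, 2.19, 2.25 and 3.10 at 0, 6, 12 and 24 h. KO minus WT was −2.13 ± 0.32 at 6 h and −2.09 ± 0.32 at 24 h, neither past the threshold (adjusted p = 0.52 and 0.57). The difference in its LPS response at 12 h was −3.73 ± 0.45, which passed only with the session (adjusted p = 0.116, then 0.0246).

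**Figure D4:**
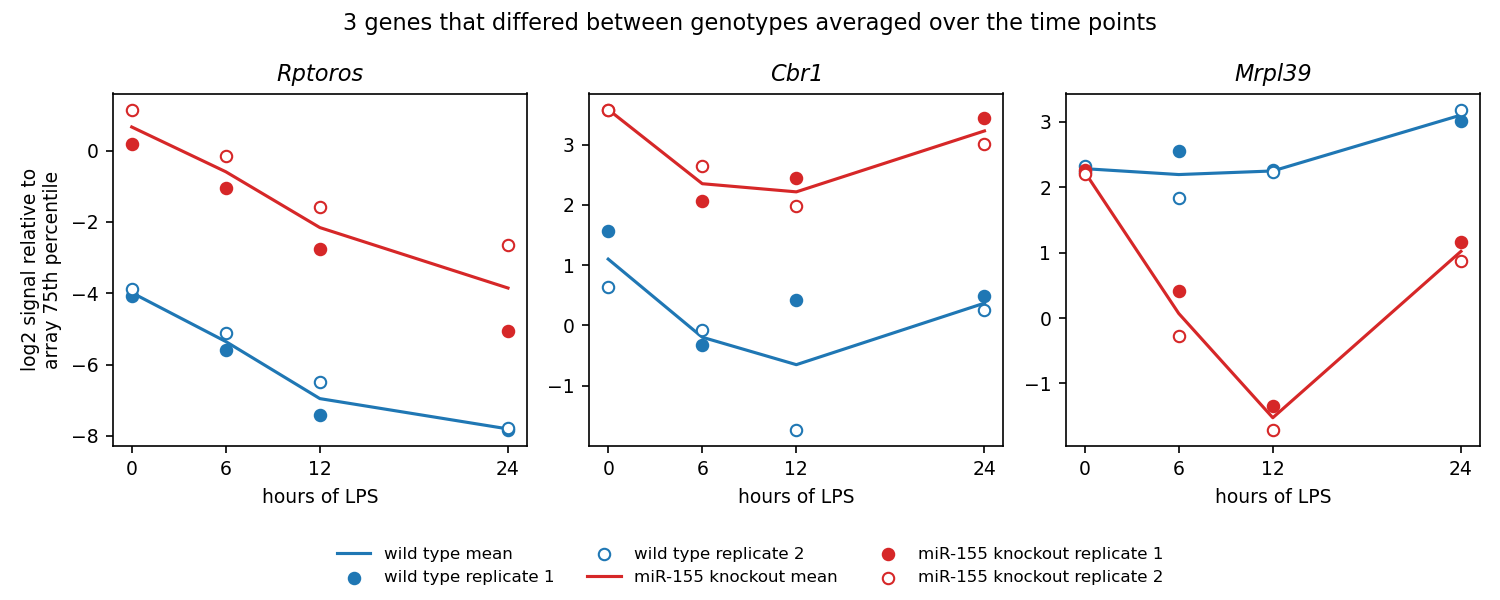
Level of Rptoros, Cbr1 and Mrpl39 on each array, in log2 units relative to the array's upper quartile, against hours of LPS, with WT and KO by colour and the scan sessions by filled and open symbols; each panel has its own scale. Averaged over time, KO minus WT was 4.54 (3.83 with bounds), 2.68 and −2.01.

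Inflammatory genes that are often measured in LPS-treated macrophages did not pass between genotypes (limma adjusted p = 1 for each). Averaged over the 4 times KO minus WT was 0.30 ± 0.75 for Tnf, 0.62 ± 0.42 for Il6, 0.59 ± 0.46 for Il1b and 0.63 ± 0.32 for Il12b. It was −0.21 ± 0.26 for Ifnb1, −0.45 ± 0.40 for Nos2 and −0.29 ± 0.97 for Il10. Among literature targets of miR-155 it was −0.11 ± 0.14 for Socs1, 0.26 ± 0.19 for Inpp5d, 0.23 ± 0.27 for the transcription factor Cebpb and −0.06 ± 0.78 for Bach1. It was 0.31 ± 0.18 for the transcription factor Spi1, 0.31 ± 0.21 for the chromatin gene Jarid2 and 0.32 ± 0.34 for Csf1r. These averages include 0 h, when Il6, Il12b, Ifnb1 and Nos2 were not well above background in either genotype. Within the 8 pairs of the same time and session, KO was higher in 8 for Tnf (0.06 to 0.59) and Arg2 (0.29 to 1.35). The same held for Spi1 (0.05 to 0.66) and Csf1r (0.10 to 0.60). KO was higher in 7 for Il6, Il1b, Il12b, Inpp5d, Cebpb and Jarid2, in 5 for Arg1 and in 4 for Il10 and Bach1. It was higher in 3 for Socs1 and in 2 for Ifnb1 and Nos2. With the session as a term none of these genes passed, the smallest p being 0.0334 for Csf1r (adjusted p = 0.875).

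The 60 literature targets of miR-155 were also tested as a list. Averaged over the 4 times, limma passed 0 of them (0 adjusted over the list alone), 39 lay above 0 and the median was 0.11 (0.07 in each session). Among those with the smallest p-values in the fit with the session were the tetraspanin gene Tspan14 (0.54 ± 0.14), the signal transducer Smad5 (0.50 ± 0.28), the phosphatase gene Ptprj (0.35 ± 0.18) and Picalm, a gene of endocytosis (0.44 ± 0.22). The standard errors in this paragraph are those of the fit without the session. The largest differences were those of Arg2 (0.77 ± 0.74) and the transcription factor Ets1 (0.68 ± 0.62). Pacs2 was below 0 (−0.23 ± 0.13). With the session Tspan14 passed over the list alone (adjusted p = 0.0349). Camera called the list higher in KO (adjusted p = 0.0119), and the call was lost with an estimated correlation (adjusted p = 0.123). The mean difference was 0.101. Without the second KO array of 24 h it was 0.113 and camera did not pass. It was 0.055 without the first KO array of 0 h and 0.067 without the second WT array of 6 h, and camera passed. After normexp it was 0.058 and camera did not pass (adjusted p = 0.982). The list mean was higher in KO in 8 of 8 pairs of the same time and session. An exact two-sided permutation of genotype within times gave p = 0.165 (adjusted p = 0.78 over 28 lists). An exact exchange within times and sessions gave p = 0.00781, the smallest it can give (adjusted p = 0.109). It treats the 8 pairs as independent, which the labels do not settle. At 6 h the list also passed camera (median 0.12, or 0.06 after normexp with a capped background, sessions −0.02 and 0.21, adjusted p = 0.00693), lost with an estimated correlation (adjusted p = 0.175).

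**Figure D5:**
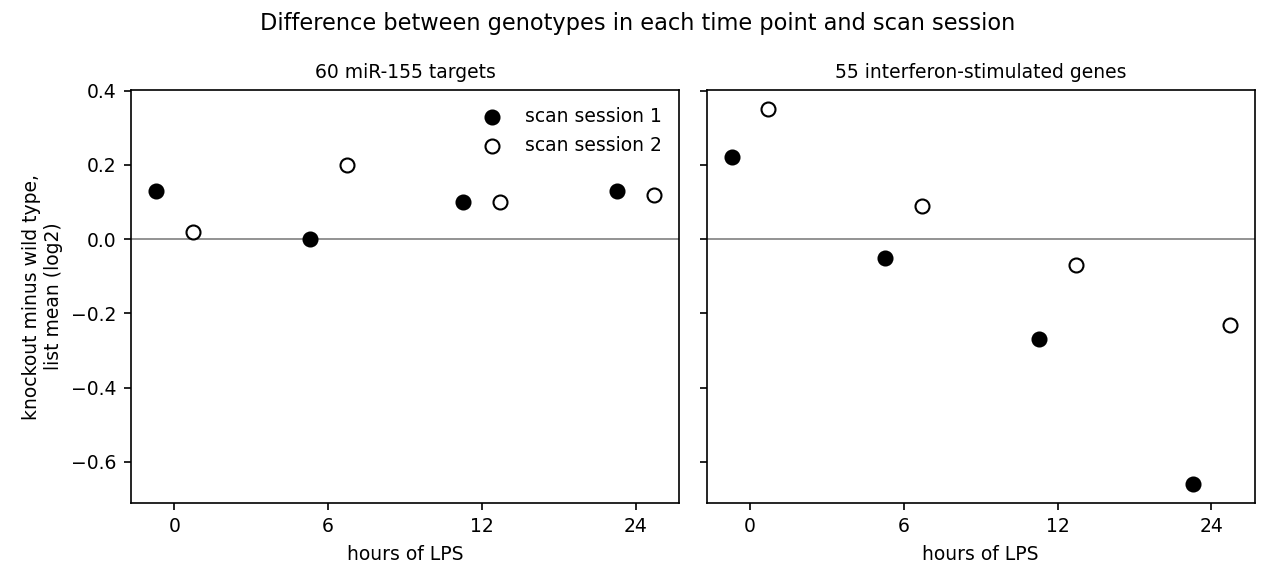
KO minus WT of the mean level of a list, in log2 units, for each pair of arrays of the same time and scan session, for 60 literature targets of miR-155 and 55 interferon-stimulated genes. The target list was between 0.00 and 0.20 in all 8 pairs, and the interferon list went from 0.22 and 0.35 at 0 h to −0.66 and −0.23 at 24 h.

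The median of interferon-stimulated genes in KO minus WT went from above 0 to below 0 with time, and no call on it held with an estimated correlation. At 0 h 50 of 55 were above 0 in KO minus WT, with a median of 0.25 (sessions 0.16 and 0.35). With the slide as a fixed block the mean at 0 h went from 0.285 to −0.006 and that at 24 h from −0.442 to −0.733, and with a random block that at 0 h was 0.13. The median was 0.04 at 6 h and −0.20 at 12 h (sessions −0.20 and −0.11). At 24 h 50 of 55 were below 0, with a median of −0.41 (sessions −0.53 and −0.21). Camera called the list at 0, 12 and 24 h (adjusted p = 4.71e-13, 0.00645 and 5.59e-09), and each call was lost with an estimated correlation (adjusted p = 0.917, 0.916 and 0.689). By limma 0 members passed at any time (0 over the list alone). The difference in LPS response had a median of −0.27 at 6 h, −0.47 at 12 h and −0.64 at 24 h, with session medians of −0.71 and −0.60 at 24 h. Camera called it at adjusted p = 0.00186, 7e-11 and 3.7e-21, again lost with an estimated correlation (adjusted p = 0.964, 0.978 and 0.545). At 24 h the difference was −1.78 ± 1.01 for the immunity-related GTPase Iigp1, −1.55 ± 0.88 for Cmpk2 and −1.45 ± 0.66 for Rsad2, which encodes viperin. It was −1.35 ± 0.93 for the antiviral gene Mx1 and −0.93 ± 0.34 for Rtp4. The mean KO minus WT of the list at 24 h was 0.049 without the first KO array of 24 h and −0.165 without the second WT array of 24 h, against −0.442 with all arrays. It was −0.72 without the first WT array and −0.933 without the second KO array of 24 h. At 0 h it was 0.03 without the second WT array and 0.098 without the first KO array, and 0.539 and 0.471 without the others of that time. The mean difference in response at 24 h, −0.727 with all arrays, was −0.236 and −1.218 without the first or second KO array of 24 h. It was −0.449 and −0.472 without the second WT array of 24 h or of 0 h. A group left with 1 array also takes on the shift of its session, and within sessions the list was at −0.66 and −0.23 at 24 h.

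Other lists that camera called between the genotypes differed by little, and none held with an estimated correlation. At 0 h antigen presentation genes (median 0.16, 26 of 31 above 0, adjusted p = 0.00116) and macrophage identity genes (0.16, but 0.04 after quantile normalization, 29 of 34, 0.00546) were higher in KO. With an estimated correlation both were at adjusted p = 0.917. At 6 h T and NK markers were lower (−0.52, or −0.36 with bounds; 0.00332), lost with an estimated correlation (adjusted p = 0.559). Alternative activation markers (−0.33; 0.0483, or 0.0741 with the session) and mast cell markers (−0.22, but −0.03 after quantile normalization; 0.0483, or 0.142 with the session) were lower at 6 h. With an estimated correlation both were at adjusted p = 0.391. Higher at 6 h were genes of Toll-like receptor signalling (0.11, but 0.07 after quantile normalization, adjusted p = 0.00693), the late LPS response (0.13, sessions −0.06 and 0.34, 0.00693), glycolysis (0.12, 0.0123) and oxidative stress (0.26, 0.0123). With an estimated correlation they were at adjusted p = 0.391, 0.559, 0.656 and 0.663. Neutrophil markers (−0.37; 0.0682, then 0.0226) and progenitor markers (−0.29; 0.273, then 0.0175) passed at 6 h only with the session, and with an estimated correlation besides both were at adjusted p = 0.389. Most of the decreases at 6 h depend on the background correction. After normexp with a capped background the medians were −0.06 for T and NK, −0.03 for neutrophil, −0.03 for mast cell, −0.01 for progenitor and −0.12 for alternative activation markers.

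Cell cycle genes were lower in KO at 12 h (median −0.25, but −0.08 after normexp, sessions −0.25 and −0.24, adjusted p = 0.00262), lost with an estimated correlation (adjusted p = 0.916). At 24 h dendritic cell markers were lower (−0.34, but 0.17 after normexp background correction, adjusted p = 0.0327), as were apoptosis regulators (−0.21, 0.00858). With an estimated correlation these were at adjusted p = 0.624 and 0.698. Averaged over time, alternative activation markers were lower (−0.17, but 0.00 after normexp, adjusted p = 0.024) in 7 of 8 pairs, lost with an estimated correlation (adjusted p = 0.292). Oxidative stress genes were higher (0.20, 7 of 8 pairs, 0.0272), and so were late LPS genes (0.15; 0.0272, or 0.0505 with the session). With an estimated correlation both were at adjusted p = 0.758. Cell cycle genes (−0.12, but 0.00 after normexp; 0.055, then 0.0478) and dendritic cell markers (−0.18, but 0.04 after normexp; 0.055, then 0.044) passed only with the session, and with an estimated correlation besides they were at adjusted p = 0.737 and 0.496. Of the 20 listed neighbours of Mir155, 1 fell averaged over time, Mrpl39 (1 rose and 1 fell over the list alone; median 0.01).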

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

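The tests of Mrpl39 for a sequence difference, for the scan session and for the slide, and that of the interferon list for correlated members, were chosen after the result was seen. Lists, Mrpl39, Noxa1 and Sod3 were singled out because the response to LPS differed between KO and WT by a test of the difference itself. The count of genes between genotypes and the chromosome 16 genes rest on KO against WT averaged over times. Among lists, camera called interferon-stimulated genes, with medians of −0.27 at 6 h (47 of 55 below 0), −0.47 at 12 h (52) and −0.64 at 24 h (52). It called glycolysis and hypoxia genes at 6 h (0.19, 21 of 28 above 0, sessions 0.26 and 0.12; adjusted p = 0.00313) and T and NK markers at 6 h (−0.61, but −0.26 after normexp with a capped background, 6 of 8 below 0, sessions −0.26 and −1.34; 0.00665). It called antigen presentation genes at 12 h (−0.33, 26 of 31 below 0, sessions −0.12 and −0.48; 0.0188) and 24 h (−0.31, 25 of 31, sessions −0.50 and −0.31; 0.0241, or 0.0508 with the session), and apoptosis regulators at 24 h (−0.23, 25 of 33, sessions −0.35 and −0.13; 0.00327). With an estimated correlation none passed, at adjusted p between 0.545 and 0.978. LXR targets passed at 12 h only with the session (−0.12, 15 of 20 below 0; 0.0973, then 0.0292, and 0.777 with an estimated correlation besides). Among genes, and only with the session as a term, Mrpl39 differed at 12 h (−3.73; adjusted p = 0.0246), and the joint test over times passed for Noxa1 (fitted −2.56 at 6 h; 0.049) and Sod3 (fitted 2.73 at 12 h; 0.0415). These fitted values include groups not well above background, so no fold can be given for either difference in response. Noxa1 was well above background on both arrays of WT at 6 h only (mean −4.50), where KO was at least 2.44-fold lower, and Sod3 on both arrays of KO at 12 h only (mean −5.14), where KO was at least 1.7-fold higher.

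The count of genes that differ between KO and WT averaged over times was compared with other splits of the 16 arrays that exchange genotype within times. Of 100 splits drawn from 648 possible, 21, the real one among them, called at least the real 3 genes, and the highest of the others called 7610, so chance is not excluded for that count. Splits that followed the scan session called the most. With 7 of the 8 relabelled arrays in session 1 the 2 splits called 5813 and 6966 genes, and with 6 the counts reached 7610, which points to the session as a structure of the samples. Splits with 4 arrays from each session, like the real one, called 0 to 8 genes, and 6 of those 30, the real one again among them, called at least 3. With the session as a term and genotype exchanged within pairs, 2 of 100 splits from 128 possible called at least the real 4. They were the real split and the highest of the others, which called 5. In that other split 6 of the 8 arrays of each group shared a real genotype. That share is under 5%, which argues against chance for that count only if the pairs are independent, and the labels do not settle that. Chance is not excluded, since another split called more genes than the real one, although that split kept much of the real contrast.

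Mrpl39 was lower in KO after LPS and not before it. A sequence difference under the probe would lower it at all times, and the tables argue against that, with KO minus WT of −0.04 at 0 h (standard error 0.32). The difference in response at 12 h was −3.64 in the session nearer 0 and −3.83 in the other, which argues against the session. It does so only weakly, since the gene was chosen by tests that favour agreement between sessions. Within single slides, KO with LPS against KO at 0 h or WT of the same time gave 4 comparisons between −2.49 and −1.33 (standard error 0.45), which argues against the slide, although at 12 h the genotypes shared no slide. The other 19 measured neighbours of Mir155 had a median of −0.07 at 12 h (−1.42 to 0.43), which argues against a change shared by most of these listed genes. A median over the others cannot speak to a change limited to Mrpl39, itself a listed neighbour of Mir155, or to a few genes close to it. The list reaches far along the chromosome, with the Usp25 probe at 77116439 and the Mrpl39 probe at 84718622 in mm9. With 1 probe across an exon junction, a change in splicing and a change in the amount of transcript stay open. Whether the absence of miR-155, or the deletion next to this gene, acts on it was not tested.

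Cbr1 and Mrpl39, which differ between KO and WT, lie on chromosome 16 with Mir155, as does Chaf1b (−1.05 ± 0.21, lower in 8 of 8 pairs; adjusted p = 1, or 0.0628 with the session). The other genes called lie elsewhere, Rptoros on chromosome 11 and Btbd11, called only with the session, on chromosome 10. The count that follows leaves out Cbr1, Mrpl39 and Chaf1b and also Adamts1 (1.21 ± 0.31) and Ifnar1 (0.25 ± 0.14), which lie in the same window at unadjusted p of 0.000345 and 0.0424 and had been noticed first. Of the 113 remaining genes within 15 Mb of the Mrpl39 probe, 13.3% (15 genes) were at unadjusted p under 0.05 with the session as a term, against a median of 5.31 and a highest of 12.4% over 15135 windows of as many neighbouring genes. That highest share was reached on chromosomes 4 and 19 and on another part of chromosome 16, from 37510094 to 64765790. The windows elsewhere also leave out Slc15a2, noticed first as well (2.47 ± 0.54, unadjusted p of 0.000417 with the session). It lies at 36750603, beside that part of chromosome 16, so the highest share elsewhere may be understated. These values are consistent with a chromosome segment that differs between the KO and WT mice, such as flanking DNA from the strain in which the gene was deleted, but the labels do not give that strain and none of the 15 passed an adjusted p. Their differences ran from −0.95 (Pcp4) and −0.94 (A930006K02Rik) to 0.66 (Cfap298). A share of session effects could not be told apart, as the correlation of the sessions' differences over the window was 0.27, against a median of 0.21 and a 95th percentile of 0.46 elsewhere.

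The median LPS response of interferon-stimulated genes at 24 h was lower in KO (−0.64), a difference that includes the higher median of KO at 0 h (0.25), and neither call held with an estimated correlation. With the slide as a fixed block the mean at 0 h went from 0.285 to −0.006 and that at 24 h from −0.442 to −0.733, while that of the difference in response stayed at −0.727. Scaling and background correction are argued against, since the median stayed between −0.79 and −0.61 under 4 alternatives. A smaller response of all induced genes stays open. The list's median lay at the 0.08th percentile of 10000 lists matched on response and level (their median −0.43, lowest −0.78). Such lists draw independent genes, while the members have an estimated correlation of 0.43, so that the bound set in advance on that percentile was too loose. The lists were also matched on the WT response at 24 h that the difference subtracts. Genes picked for a high measured WT response tend to show a lower KO response for that reason alone. The comparison therefore cannot decide the question. Correlated members read on few arrays also stay open, as camera with an estimated correlation gave adjusted p = 0.545. That correlation was estimated in the fit without the session, so it also holds the shift between sessions. The response was smaller in KO in both sessions for 52 of 55 members. Members that vary together do not count as separate evidence. A lower interferon response in KO may therefore be a shift of correlated genes on a few arrays.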

How the results depend on the processing

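Normexp with a capped local background, fry and the exact exchange for the targets, and running the alternatives on 3 shifts of the interferon-stimulated list between genotypes, were chosen after seeing the data, while the list itself and its camera tests were planned. Of 30049 values of named genes under the alternatives, 27511 kept direction and side of the threshold, 2445 lost the call, 73 gained it and 20 changed sign. Series table values, array weights, quantile normalization, the choices of probes, moderation and the added 2-fold threshold kept every count of LPS genes within 1.5 times.

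Normexp lowered the counts to 512, 216 and 102 in WT at 6, 12 and 24 h and 15 for 24 h against 6 h, and to 425, 146, 73 and 3 in KO. KO against WT gave 0 at 12 h and 0 averaged (Mrpl39 −1.49, Rptoros 1.75, Cbr1 2.25), and the targets 0.058. It changed the sign of Adamts1 (0.60), Il1rl1 (0.38), Irf4 (1.01), Ppbp (1.51), Rhd (1.06) and Tlr5 (1.13) in WT at 12 h. In KO at 12 h it changed that of Acta2 (−0.02), Fcrla (0.82), Il1rl1 (0.09), Irf4 (0.71), Rhd (0.83), Tlr5 (0.57) and Wee1 (0.94). In KO at 24 h it changed that of Fcrla (0.03), Ppbp (0.17), Prtn3 (0.47), Rhd (0.05) and Wee1 (0.20), and in KO between 6 and 24 h that of Rhd (0.02). The share of higher genes became 64.8% and 67.6% in WT at 6 and 24 h and 59.1% and 37.7% in KO at 6 and 12 h. The cause is in the correction, where a few spots with a local background of up to 723000 raised the 5th percentile of signal to 3020, 3280 and 236 on 3 arrays, against 55.4 to 77.5 on the others. With the background capped near its top, LPS counts stayed within 1.5 times, KO against WT gave 1 at 0 h and 1 at 12 h, and Ppbp in WT at 12 h was 0.18.

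With the session as a replicate block the counts were 8047, 6645, 4842 and 5312 in WT, 7719, 6772, 4261 and 5673 in KO, 1 and 2 for KO against WT at 0 and 6 h and 2 for the joint test. Beyond the calls given with their results the block changed no other call in the lists and genes printed. With the slide as a fixed block they were 8429, 5284, 5200 and 5885 in WT and 8163, 5531, 4413 and 4430 in KO, Cbr1 lost its call (2.67), and the interferon list at 0 h was −0.006. With a random block (correlation 0.596) they were 8346, 6091, 5296, 5924, 8176, 6066, 4586 and 5087, with 1 for KO against WT at 0 h and 7 averaged. Each slide was scanned in 1 session, so the fixed block takes out the session and slide differences besides. Only the arrays compared gave 2627, 1409, 778 and 31 in WT, 1883, 1012, 0 and 0 in KO and 0 for KO against WT at 12 h, with fewer degrees of freedom. Scaling to the median gave 2181 and 928 in WT at 12 h and for 24 h against 6 h, 3005, 2246, 1093 and 1082 in KO, and 1 for KO against WT at 12 h. That count was also 1 with probes well above background on all 16 arrays and with trended and robust moderation. For these the cause was not tested. Scaling to the median moved the median of all genes from −0.03 to 0.33 in WT at 24 h, and quantile normalization from 0.06 to −0.15 in WT at 6 h.

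Of 90 list calls for LPS, 16 held with an estimated correlation and 85 with fry, and of 28 between genotypes 0 and 0. These include the targets (0.101; adjusted p = 0.123 and 0.43, and 0.109 by exact exchange), and interferon genes at 0 h (0.285; 0.917 and 0.989), at 24 h (−0.442; 0.689 and 0.993) and in the response (−0.727; 0.545 and 0.987). Of the medians of 129 called lists, 2 changed sign after quantile normalization, 6 changed sign or became 0 after normexp, and 0 after median scaling or capped normexp. Of the others, quantile normalization made 15 over 1.5 times smaller and 3 larger, median scaling 8 and 13, normexp 44 and 5, and capped normexp 33 and 1.

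Leaving out 1 array, with the lone sample assumed to vary like other groups, gave 2764 to 4471, 1713 to 3358, 801 to 1913 and 552 to 1757 genes in WT, 2969 to 4523, 1706 to 3358, 759 to 1638 and 925 to 2123 in KO. For KO against WT it gave 0 to 0 at 0 and 6 h, 0 to 5 at 12 h, 0 to 1 at 24 h (1 without the second WT array of 24 h), 2 to 4 averaged, and 0 to 3 in the joint test (3 without the second WT array of 12 h). Targets ranged from 0.055 to 0.146, and interferon genes from 0.03 to 0.539 at 0 h, −0.933 to 0.049 at 24 h and −1.218 to −0.236 in the response, the last bound and the change of sign both without the first KO array of 24 h. A group left with 1 array also takes on the shift of its session. Signal over background limits what dim genes show: 13664 genes were well above background on all 16 arrays. The search of 3′ untranslated regions was not run.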

Other observations

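Each gene that responded to LPS was also placed by the time of its largest change. Of 5456 genes called at any time in WT, the largest change came at 6 h for 1684 rises and 1639 falls, at 12 h for 635 and 766, and at 24 h for 235 and 497. In WT the endothelin gene Edn1, at its highest at 6 h, was still at least 723-fold above 0 h at 12 h, and Ifnb1 at least 102-fold at 12 and at 24 h. In KO between 6 and 24 h the interferon-induced sensor Ifih1 changed by −2.90, Gbp5 by −3.58, the death ligand Tnfsf10 by −3.78 and the cytokine gene Il27 by −5.32.

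Camera called literature targets slightly higher in KO, a call lost with an estimated correlation (adjusted p = 0.123) and not reached by exact exchange (adjusted p = 0.109), and limma passed 0 of 60. Whether direct pairing could contribute to such a difference was tested on the probes, a test set before its result was seen. The 106 genes whose probe of 60 bases holds a match to the miR-155 seed had a mean KO minus WT of 0.022, against −0.016 over all genes, and stood at the 94.6th percentile of 10852 words of 7 bases (0.038 above the rest after adjustment for GC content and level). That lies above the median and below the 95th percentile named in advance, so the test leaves direct pairing open, and probes cover only a small part of each transcript.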
